A study of Bos taurus with 3 samples.

How the data were processed

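Nuclei had been isolated from snap-frozen cells and processed with the 10x Genomics Chromium 3' chemistry, per the labels' protocols, with about 10,000 nuclei per sample as the target. The libraries were sequenced on an Illumina NovaSeq X+ instrument. Reads were turned into UMI counts per gene and nucleus by the authors with Cell Ranger 9.0.0, per the submitters' processing notes. The deposited values are whole-number counts in filtered matrices, not normalized, for 27270 genes named by Ensembl identifier and, for all but 6922, a symbol. The genome build and annotation are not given in the sources used here, so no coordinates are given. The labels mention a multi-omic submission, and only the transcriptomic counts were used here. Every sample title carries the same replicate word, and the library names have no stated meaning, so the 3 libraries were taken as 1 group and numbered 1 to 3 in the order of their records. Counts of each pair of libraries differed far beyond sampling noise (chi-square per degree of freedom 111, 150 and 121), so none was a copy of another.

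Barcodes with fewer than 500 detected genes (31, 128 and 313 in replicates 1, 2 and 3) or with at least 5% of UMIs from the 13 mitochondrial protein genes (27, 44 and 46) were removed, which left 31322 of 31911. Doublets were scored per library with scrublet in scanpy 1.11.5. Its automatic threshold marked 497, 0 and 0 nuclei, so it had not worked in replicates 2 and 3, and the 8% of nuclei with the highest scores in each library (739, 935 and 832) were removed instead, a share set after the data were seen. This left 28816 nuclei. A pair of genes without a symbol, ENSBTAG00000043567 and ENSBTAG00000043570, took 2.65% to 3.01% and 1.14% to 1.46% of UMIs per library.

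Clusters were built from 2000 variable genes. Every fixed list, cell type marker and mitochondrial protein gene was left out, so that these genes were measured apart from the clustering. ENSBTAG00000043567 and ENSBTAG00000043570 were not left out and were among the genes used. Counts were scaled to 10000 per nucleus, log-transformed, centred and scaled within each library and clipped at 10 SD. A graph of 15 neighbours in 30 principal components was partitioned with the Leiden method at a resolution of 0.5. A cluster was named when at least 3 markers of a class were at least 2 times the level of the other nuclei and at 10 CPM or more, when these outnumbered the markers of that class that were lowered, and when no other class had as many raised markers. Clusters with a median depth under 0.333 of that of their own library and none of the markers among their leading genes stayed unnamed. These conditions were set after marker levels in exploratory clusters had been seen. Where no cluster had the name, the cluster with the highest mean log2 CPM of the markers was compared. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, and the limit that a count of 0 allows was taken as 3 counts.

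UMI counts were summed per library and cluster, over the 10 clusters with at least 30 nuclei in every library, which left out cluster 11. The 30 sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, library as a block, 18 residual degrees of freedom, 14025 genes tested) under R 4.3.3. Each contrast is 1 class or cluster minus the mean of the other clusters with equal weight, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Levels given for the other clusters are likewise means over clusters. Since clusters were derived from the same nuclei, counts of genes exclude clustering genes, and p-values between clusters still overstate independence. The block matches the sums of 1 library with each other by construction. Gene sets were tested on the same fit with camera in limma 3.58.1 (correlation preset to 0.01, then estimated) and fry. DESeq2 1.42.0 served as an alternative test and source of size factors. The 21 lists and 10 marker sets, the comparisons, the tests and all alternatives not named as later additions were chosen before the data were examined. The sex-linked list had no members in the matrices analysed here.

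Named genes followed a rule fixed at the same time. It took, for each list described, the 3 members with the largest rise and the 3 with the largest fall that passed the test with 1 direction in all 3 libraries, taken from mean log2 levels over clusters. It added the 5 largest rises and falls among other genes that had a symbol, reached 20 CPM, met the same conditions and were not used for clustering. A set of genes was always named (CSH2, PAG1, PAG2, IFNT2, CDX2, GATA3, GCM1, MKI67, CYP11A1 and STAR). Which lists are described gene by gene was decided after the results and their alternatives were seen, and the alternatives are therefore also counted over all genes that the rule can name. The symbol PAG1 belongs to 2 rows. In the RefSeq gene table of assembly ARS-UCD2.0, used for neighbours only, ENSBTAG00000014026 lies at the place of the adaptor gene PAG1, and it was left out of the glycoprotein list after the data were seen.

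The testing steps were tried on simulated counts with 200 changed genes among 14025. In the binucleate-like comparison, 46% of genes changed 2-fold and 74% of those changed 4-fold were recovered. The shares were 83% and 95% in the cluster 1 comparison and 88% and 92% in the cluster 6 comparison. Of unchanged genes, 5, 16 and 9 were called. Genes were drawn independently of each other from a shared composition, and the clustering was not repeated. These calls therefore do not give the rate of false calls in the real comparisons.

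Nuclei were ordered by diffusion pseudotime with 10 components from the nucleus nearest the centre of cluster 6, and marker sums were taken in 10 equal bins per library. Alternatives covered the normalization, the gene filter, the test, the block, each replicate left out, thinning of nuclei to 2000 UMIs, doublets kept, a minimum of 1000 genes, resolutions of 0.3 and 1.0, 4000 variable genes, no centring within libraries, list genes allowed in the clustering, and 5 or 20 bins and 5 or 15 components. Thinning left 8225, 8986 and 8110 nuclei and set aside 276, 1766 and 1453 shallower ones. Added after the data were seen were fits without clusters 5, 7 and 9, fits with clusters of at least 10 nuclei per library, contrasts for clusters 2, 3, 8 and 11 and the mononucleate class, and a version of the cluster 6 comparison and of the ordering with names that ignore lowered markers, which puts cluster 3 in the place of cluster 6. Computations used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.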

Results

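Single-nucleus transcriptomes were collected from bovine trophoblast stem cells, self-renewing progenitors of the placenta derived from blastocysts, after 10 days of directed differentiation. The cells had been grown on collagen IV with a ROCK inhibitor and forskolin, an activator of adenylyl cyclase that raises cAMP. All 3 libraries, here replicates 1 to 3, belonged to 1 group, and nothing in the labels says that they came from separate cultures. Each p-value below therefore rests only on how differences between clusters vary from 1 of these libraries to another. All clusters share 1 estimate of this spread, which may be technical. The stated purpose was to describe how heterogeneous the day-10 cells are and how they differentiate, so the comparisons are between classes of nuclei within the libraries. The deposited matrices held 9298, 11859 and 10754 nuclei with 71123656, 77995571 and 60622447 unique molecular identifiers (UMIs) in replicates 1, 2 and 3. Median depth was 5278, 4430 and 4047.5 UMIs per nucleus. After removal of shallow nuclei and the nuclei with the highest doublet scores, 8501, 10752 and 9563 nuclei remained.

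Hormone-producing nuclei formed a rare cluster, and most nuclei lay in clusters without a name. Nuclei fell into 11 clusters, built from genes outside every fixed list and marker set, and 3 of these earned a cell type name. Cluster 10 was binucleate-like, resembling the hormone-secreting binucleate cells of the ruminant placenta, with 22 raised markers. It made up 1.58% of nuclei in replicate 1 (exact 95% binomial interval 1.32 to 1.86, 134 nuclei), 0.279% in replicate 2 (0.188 to 0.398, 30 nuclei) and 0.972% in replicate 3 (0.786 to 1.19, 93 nuclei), a mean of 0.943% ± 0.649 (SD, n = 3). Clusters 2 and 8 were mononucleate trophoblast-like, resembling the mononucleate cells that secrete interferon tau and trophoblast Kunitz domain proteins, and held 25.2%, 20.2% and 23.9% of nuclei (23.1% ± 2.60, SD, n = 3). IFNT2 and TKDP1 did not single these clusters out: IFNT2 stood at 24.1 ± 22.3 CPM (counts per 1000000 UMIs; SD, n = 3) in cluster 2 and 38.6 ± 22.9 in cluster 8 against 76.5 ± 93.5 in cluster 4, and TKDP1 at 5429 ± 207 and 2891 ± 722 against 4841 ± 418. The remaining 75.9% ± 3.23 of nuclei lay in 8 clusters without a name. The naming rule, completed after the data were seen, gave no cluster a cycling-like, trophoblast stem-like, mesenchyme, endoderm, epiblast, endothelial, immune or neural name. Cluster 3 (23.5%, 17.7% and 14.1% of nuclei, mean 18.4% ± 4.73) had 3 raised stem markers but also 3 lowered ones. Cluster 9 (1.09%, 0.725% and 0.931%, mean 0.917% ± 0.185) had 4 raised mononucleate and 4 raised mesenchyme markers, a tie that the rule leaves unnamed. Missing names also depend on the clustering. With list genes allowed in it, 16.9% of nuclei lay in a cycling-like cluster, which took 57.1% of its nuclei from cluster 1. At a resolution of 0.3, 42.1% of nuclei lay in a trophoblast stem-like cluster. Its largest part, 45.2%, also came from cluster 1. Without centring of the libraries the mononucleate share was 37.5%. The intervals cover counting error only.

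**Figure D1:**
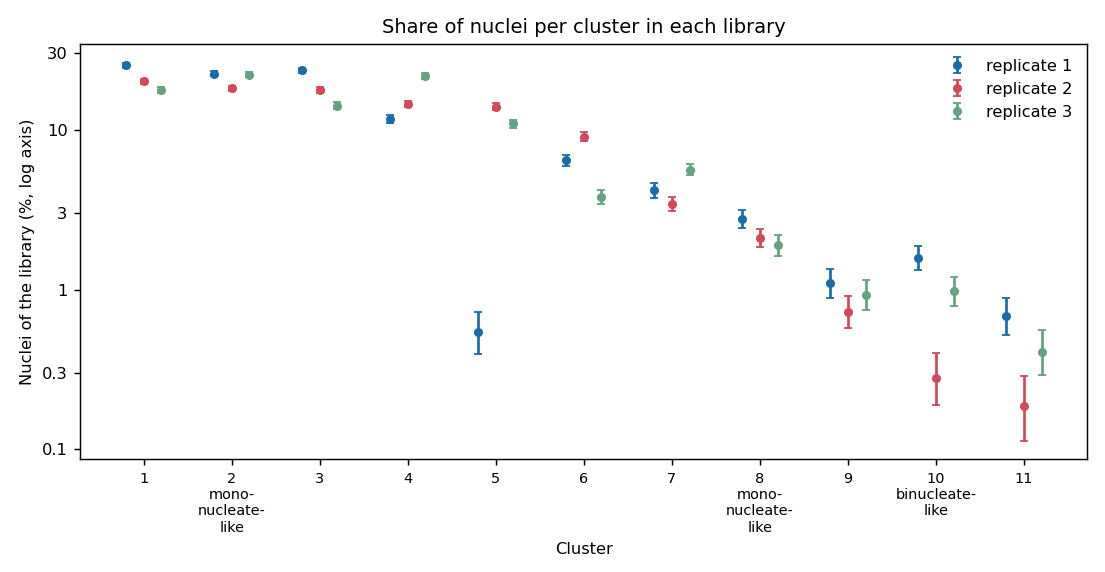
Percent of the nuclei of each library (log axis) in each of the 11 clusters, with 1 point per replicate and exact 95% binomial intervals as bars. Cluster 10 ranged from 0.279% in replicate 2 to 1.58% in replicate 1, and cluster 5 from 0.541% in replicate 1 to 13.9% in replicate 2.

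The genes that set each cluster apart were in large part used to build it and serve here only to identify it. Cluster 1 was led by PPP1R1C, LRIG1 and RDH12, cluster 2 by ADAM28, SORBS2 and CALCRL, and cluster 3 by TRPC4, ENPP3 and PCDH17. Cluster 4 was led by PINLYP and by the interferon tau gene IFNT2, and cluster 6 by EMP1, PELI2 and CDH17. Cluster 8 was led by MMP9 and SPP1, cluster 10 by PRP3, FST and ESM1, and cluster 11 by GNG2, ATP6V1B1 and FOXI1. Cluster 5 (0.541%, 13.9% and 10.9% of nuclei) had a median of 916 UMIs, cluster 7 was led by mitochondrial transcripts such as ND3 and ATP8, and cluster 9 was led by COL1A1 (155 against 2.69 CPM), SPARC, COL1A2 and COL3A1, genes of mesenchymal matrix, mostly from replicate 3 (COL1A1 at 53.8, 7.83 and 424 CPM and mesenchyme markers at 107, 54.8 and 771 CPM in replicates 1, 2 and 3). Ribosomal protein transcripts were also among the leading genes of cluster 9, whose median share of mitochondrial protein transcripts was 1.02%. ENSBTAG00000043570, without a symbol and used for clustering, stood at 157316 CPM in cluster 9 against 10674 CPM elsewhere. In cluster 7, ENSBTAG00000043567, also used for clustering, stood at 80139 CPM against 25235 CPM elsewhere. Clusters 5, 7 and 9 were kept in the comparisons, and each leading count was computed again without them.

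At the level of whole libraries, the conceptus secretory genes were the most abundant fixed list, at 7627 ± 915 CPM (SD, n = 3), with TKDP1, a trophoblast Kunitz domain protein, as the highest member. The pan-trophoblast epithelium list summed to 4149 ± 540 CPM, with KRT8 highest, and the trophoblast stem cell (TSC) transcription factors to 3501 ± 174 CPM, with YAP1 highest. The ancient pregnancy-associated glycoproteins (PAGs), which are made across the trophoblast, reached 1645 ± 213 CPM and were led by PAG2. The modern PAGs, which are known from binucleate cells, reached only 28.3 ± 16.3 CPM, and the binucleate cell hormones, prolactin-related proteins and placental lactogen, 69.2 ± 46.7 CPM. Both were lowest in replicate 2, at 9.86 CPM for modern PAGs against 40.5 and 34.7, and at 15.3 CPM for hormones against 94.2 and 98.1.

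Proliferation and housekeeping lists varied less between libraries, relative to their means, than the binucleate cell hormones and modern PAGs did. Mitosis genes summed to 2479 ± 158 CPM, S phase genes to 1542 ± 99.5, cytokinesis genes to 1556 ± 59.3 and endocycle and arrest genes to 519 ± 92.5. Syncytium and fusion genes summed to 2627 ± 287 CPM, transporters to 2173 ± 33.8, matrix and integrin genes to 1757 ± 167, cholesterol synthesis to 1701 ± 84.4 and steroid synthesis to 787 ± 30.9. Hypoxia and glycolysis genes summed to 1252 ± 136 CPM, stress and apoptosis genes to 1097 ± 79.1, imprinted genes to 852 ± 193, cAMP response genes to 218 ± 60.2 and interferon response genes to 116 ± 44.5 (SD, n = 3 throughout). Among markers of other cell types, endoderm markers summed to 202 ± 52.2 CPM, of which GATA6 gave 92.9%, epiblast markers to 253 ± 50.2 and endothelial markers to 132 ± 64.6, of which FLT1 gave 89.3%. Immune markers stood at 37.7 ± 3.90 CPM, mesenchyme markers at 27.5 ± 5.01 and neural markers at 23.9 ± 6.63. The marker sets used for naming summed to 97.1 ± 62.6 CPM for binucleate, 8067 ± 1144 for mononucleate trophoblast, 1531 ± 88.1 for stem and 1462 ± 125 for cycling markers. Sex-linked genes were not analysed here.

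**Figure D2:**
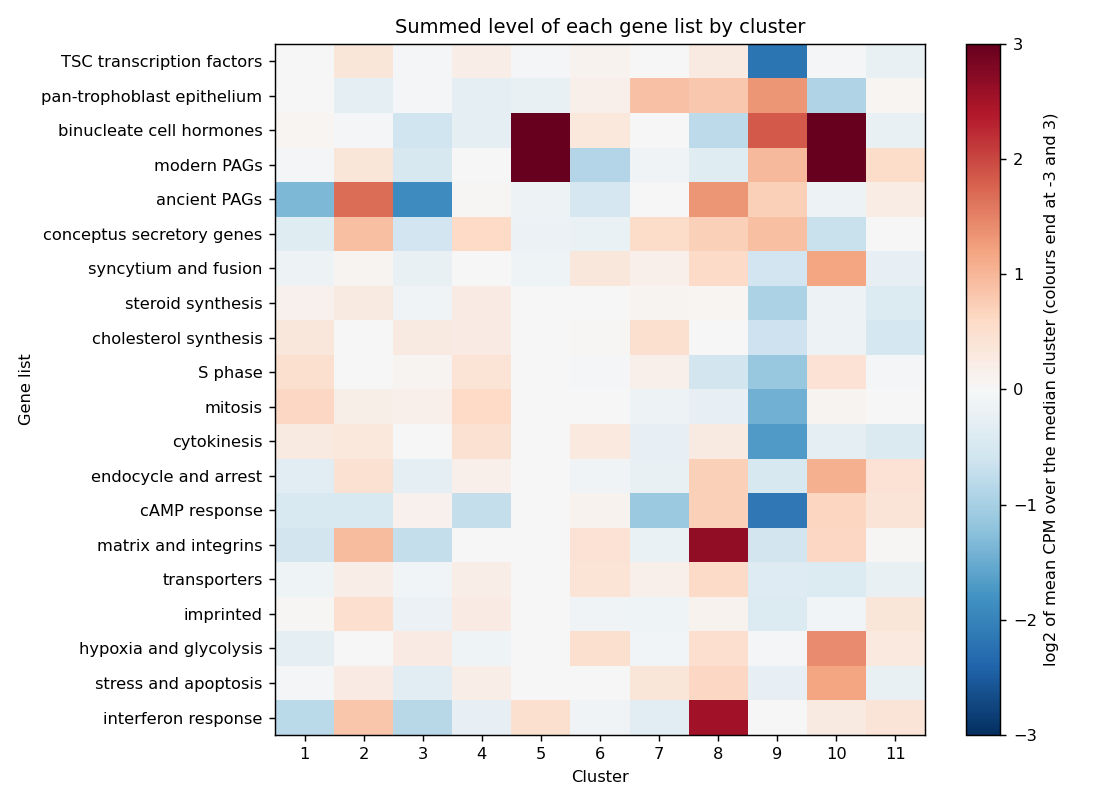
Summed level of each of the fixed gene lists in each cluster, as log2 of the mean CPM over 3 libraries divided by that of the median cluster, with red for higher and blue for lower levels. Binucleate cell hormones averaged 5687 CPM in cluster 10 and 105 ± 125 CPM in the shallow cluster 5. In cluster 5 they stood at 246, 8.51 and 59.6 CPM in replicates 1, 2 and 3, of which replicate 1 gave only 46 nuclei. Most other lists lay near 0 in most clusters.

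The first comparison asked how binucleate-like nuclei differ from the rest of the culture. Placental hormones and modern PAGs were almost confined to cluster 10 in these libraries. PRP3, a prolactin-related protein, stood at 2553 ± 1400 CPM (SD, n = 3) in cluster 10 against a mean of 1.66 ± 1.49 over the other 9 clusters of the fit, and CSH2, placental lactogen, at 74.6 ± 17.5 against 0.424 ± 0.224. The genes of several transcription factors known from trophoblast fusion and differentiation were also raised. GCM1, which drives syncytium formation in other mammals, stood at 155 ± 42.5 against 0.638 ± 0.286 CPM, and PPARG, a nuclear receptor, at 3689 ± 656 against 185 ± 32.0 CPM. Epithelial junction and keratin genes and most TSC transcription factors were lower.

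Of 9 hormones tested, all 9 rose and none fell. PRP3 rose by 11.98 ± 0.20 on the log2 scale (SE; adjusted p = 5.9e-27), PRP2 by 9.30 ± 0.21, PRP14 by 9.26 ± 0.16 and CSH2 by 7.80 ± 0.27. All 14 modern PAGs tested rose, among them PAG18 by 11.71 ± 0.24, PAG5 by 10.25 ± 0.30 and the PAG1 row ENSBTAG00000054180 by 11.04 ± 0.32. These 9 hormones and 14 modern PAGs are the 23 binucleate markers tested, all of which rose. Their rise restates the name of the cluster but not its construction, since none of them was used to build it. Of the 5 ancient PAGs tested, 2 rose, PAG10 by 8.22 ± 0.23 and PAG12 by 1.38 ± 0.30, and 1 fell, PAG2 (-0.98 ± 0.21; adjusted p = 3.6e-04). PAG and PRP genes are close paralogs, and reads could be shared between members, so single members are less certain than the groups. The direction for PAG12 was the same in all 3 replicates, but its level in replicate 2 was near that of the other clusters, as the plot of genes in cluster 10 shows.

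Of 17 syncytium and fusion genes tested, 7 rose and 4 fell (7 and 5 adjusted over the list alone). GCM1 rose by 8.12 ± 0.24, PPARG by 4.64 ± 0.14 and HAND1, a transcription factor of trophoblast giant cells in rodents, by 2.33 ± 0.26, while the tetraspanin CD81 (-1.64 ± 0.23), ADAM9 (-1.48 ± 0.15) and ASCL2 (-1.30 ± 0.36) fell. Among 16 endocycle and arrest genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone). CDK6, a kinase of the G1 phase, rose by 4.86 ± 0.22, E2F7 by 2.24 ± 0.25 and E2F8 by 2.23 ± 0.39, the last 2 being repressors needed for endoreduplication in the rodent placenta. CCND1 (-1.94 ± 0.42) and CDKN1A (-1.67 ± 0.48) fell. Mitosis genes showed 2 higher and 2 lower of 24, S phase genes 4 higher and 2 lower of 25 and cytokinesis genes 2 higher and 4 lower of 11 (2 and 5 adjusted over the list alone). MKI67, a proliferation marker, differed by 0.12 ± 0.18 (adjusted p = 0.66).

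The TSC transcription factors had 2 higher and 12 lower of 17 tested (2 and 13 adjusted over the list alone). TP63, a factor of basal epithelial cells, rose by 1.78 ± 0.13 and FGFR2, a receptor for fibroblast growth factors, by 1.29 ± 0.14. ELF5 (-2.54 ± 0.55), KLF5 (-1.98 ± 0.23), ESRRB (-1.42 ± 0.32), CDX2 (-0.94 ± 0.25) and GATA3 (-0.47 ± 0.15) fell. Of 13 pan-trophoblast epithelium genes, none rose and 11 fell, including the desmosome gene DSP (-1.82 ± 0.14), SFN (-1.69 ± 0.23) and the tight junction gene CLDN6 (-1.54 ± 0.16). Conceptus secretory genes had 0 higher and 4 lower of 10, and IFNT2 differed by -0.89 ± 0.64 (adjusted p = 0.31). STAR, which carries cholesterol into mitochondria, fell by 2.16 ± 0.37, and CYP11A1, the side-chain cleavage enzyme, differed by -0.51 ± 0.44 (adjusted p = 0.41). The other PAG1 row, ENSBTAG00000014026, which neighbours ZNF704 and FABP5 as the adaptor gene PAG1 does and not the glycoprotein, had a fitted change of -1.22 ± 0.39 (adjusted p = 0.013), lower in 2 of 3 replicates by mean log2 level over clusters, lower in all 3 by mean CPM, and 0.12 without replicate 1. Outside the lists and among genes not used for clustering, the largest rises were those of RNF183, PRP-VII, WNT10B, CCDC184 and CPA5. WNT10B stood at 142 ± 119 against 1.23 ± 0.190 CPM and CPA5 at 176 ± 38.1 against 1.99 ± 0.820 CPM. The largest falls were those of UBE2QL1, TMEM40, EMILIN2, ST6GALNAC1 and SHISA4, with TMEM40 at -3.28 ± 0.66.

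Of the other lists, steroid synthesis had 1 higher and 3 lower of 13, cholesterol synthesis 1 and 6 of 15 (1 and 8 adjusted over the list alone), cAMP response 2 and 2 of 13, and matrix and integrins 5 and 9 of 21 (5 and 10 adjusted over the list alone). Transporters had 3 higher and 5 lower of 18, imprinted genes 3 and 2 of 13, hypoxia and glycolysis 3 and 2 of 15, stress and apoptosis 4 and 4 of 15, and interferon response 1 and 1 of 10. For each list in this comparison with a single pair of counts, the count adjusted over the list alone was the same. By camera, hormones (adjusted p = 1.2e-88), modern PAGs (4.3e-88) and syncytium and fusion genes (0.00765) were higher as sets and the epithelium list was lower (2.6e-06). With an estimated in place of a preset correlation, hormones (adjusted p = 1.3e-07) and modern PAGs (9.0e-07) still passed. The tested members of these 2 lists are the markers that named the cluster, which favours both calls. The epithelium list had adjusted p = 0.200 with an estimated correlation, and the syncytium and fusion list adjusted p = 0.0542 with an estimated correlation. The TSC transcription factors did not pass by camera (adjusted p = 0.150). Median, mean and camera direction differed in sign for ancient PAGs (median -0.45, mean 1.52), mitosis, cAMP response, imprinted and stress genes. Of markers of other cell types, 2 of 7 mesenchyme markers (THY1 and COL3A1), 2 of 3 immune markers (CSF1R and LCP1) and 1 of 6 neural markers tested were higher in cluster 10, and 2 of 4 endoderm, 1 of 4 epiblast and 1 of 7 endothelial markers lower.

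Across all genes, edgeR called 2063 genes higher and 2056 lower in cluster 10 among the 12769 tested that had not been used for clustering. The balance was 2473 higher and 1667 lower with DESeq2 and 1877 and 2334 without clusters 5, 7 and 9. Without replicate 1, which held 134 of the 257 nuclei, 2660 were called in place of 4119 (1702 higher and 958 lower), and 2067 with nuclei thinned to 2000 UMIs and clusters of at least 10 nuclei. Replicate 2 gave only 30 nuclei to this cluster. Median UMIs per nucleus were 1.32 ± 0.0780 times those of the other nuclei (SD, n = 3).

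The second comparison asked where proliferating nuclei lie. No cluster was named cycling-like, so cluster 1, which had the highest mean log2 CPM of cycling markers, was compared with the others, but cluster 4 stood level with it (both 7.05). Mitosis and S phase genes were modestly higher in cluster 1, and conceptus secretory, ancient PAG, matrix and hypoxia genes were lower, but no list call of this comparison was kept when the correlation between genes was estimated. The mitotic kinesin KIF23 stood at 231 ± 26.1 against 119 ± 3.08 CPM in the other clusters and the mitotic kinase gene CDK1 at 138 ± 16.9 against 80.1 ± 7.65 CPM (SD, n = 3). The 12 cycling markers summed to between 400 CPM in cluster 9 and 1804 CPM in cluster 1, with 1776 CPM in cluster 4.

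Of 24 mitosis genes, 17 rose and none fell (18 and 0 adjusted over the list alone), but 11 of these genes are markers by which cluster 1 was chosen, which favours a rise. All 11 rose, and of the other 13 members 6 rose and none fell. KIF23 rose by 0.96 ± 0.10 (SE; adjusted p = 1.5e-08), the spindle checkpoint kinase gene TTK by 0.87 ± 0.11, CDK1 by 0.69 ± 0.12 and MKI67 by 0.34 ± 0.11 (adjusted p = 0.0088). Of 25 S phase genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone). CLSPN, a mediator of the replication checkpoint, rose by 0.82 ± 0.11 and the polymerase gene POLA1 by 0.76 ± 0.11. PCNA fell by 0.31 ± 0.12 (adjusted p = 0.039), a direction that turned when clusters 5, 7 and 9 were left out (0.064). Cytokinesis genes had 6 higher and 2 lower of 11. All 12 cycling markers tested rose, which the choice of the cluster by their level favours.

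TSC transcription factors moved both ways, with 7 higher and 6 lower of 17. ESRRB rose by 1.48 ± 0.13, ELF5 by 1.01 ± 0.16, KLF5 by 0.95 ± 0.14 and CDX2 by 0.89 ± 0.10, whereas ITGA6 (-1.01 ± 0.16), FGFR2 (-1.01 ± 0.14) and TP63 (-0.69 ± 0.15) fell. GATA3 differed by 0.01 ± 0.13 (adjusted p = 0.98). All 5 ancient PAGs tested fell, including PAG12 (-3.03 ± 0.35), PAG11 (-2.09 ± 0.28) and PAG2 (-1.26 ± 0.20). Of 21 matrix and integrin genes, 3 rose and 14 fell (3 and 15 adjusted over the list alone). The fibronectin receptor subunit gene ITGA5 rose by 0.86 ± 0.14, while TIMP3 (-3.55 ± 0.34), ITGA2 (-3.30 ± 0.33) and the gelatinase gene MMP9 (-2.43 ± 0.55) fell. Of 15 hypoxia and glycolysis genes, none rose and 9 fell, among them ADM (-3.55 ± 0.54), NDRG1 (-2.60 ± 0.35) and EGLN3 (-2.47 ± 0.26). CYP11A1 fell by 1.72 ± 0.28, GCM1 by 2.63 ± 0.62 and CSH2 by 1.40 ± 0.52, the last 2 from levels near 0 in most clusters, and STAR differed by -0.13 ± 0.13 (adjusted p = 0.44). IFNT2 had a fitted change of -1.42 ± 0.38 (adjusted p = 0.0026), lower in 2 of 3 replicates by mean log2 level over clusters and in all 3 by mean CPM. The adaptor-like PAG1 row rose by 1.56 ± 0.19, and the glycoprotein row, with only 4 counts in cluster 1, had a fitted difference of 0.57 ± 0.40 (adjusted p = 0.28) against its mean levels, 0.119 ± 0.0809 and 10.1 ± 3.34 CPM elsewhere. Outside the lists and among genes not used for clustering, RDH12 (2.47 ± 0.15), GDPD2 (2.15 ± 0.18), the growth factor gene EREG (2.05 ± 0.19), MYLK and TNFRSF19 rose most. TINAGL1 (-4.03 ± 0.24), RASSF9 (-3.55 ± 0.31), CITED1, TXNIP and C15H11orf96 fell most.

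Conceptus secretory genes had 0 higher and 7 lower of 10, syncytium and fusion genes 2 and 11 of 17 (3 and 11 adjusted over the list alone), cAMP response 1 and 7 of 13, and interferon response 0 and 7 of 10. Transporters had 3 higher and 9 lower of 18, stress and apoptosis genes 0 and 7 of 15, endocycle and arrest genes 3 and 8 of 16 (4 and 8 adjusted over the list alone), and the epithelium list 1 and 7 of 13. Hormones had 0 higher and 5 lower of 9 (0 and 6 adjusted over the list alone), modern PAGs 0 and 3 of 14, steroid synthesis 3 and 3 of 13, cholesterol synthesis 5 and 1 of 15 and imprinted genes 3 and 3 of 13. For each list in this comparison with a single pair of counts, the count adjusted over the list alone was the same.

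By camera, mitosis (adjusted p = 9.0e-04) and S phase genes (0.00256) were higher as sets, the mitosis list with the markers that chose the cluster, and 9 lists were lower: matrix and integrins (7.0e-05), ancient PAGs (9.0e-04), hypoxia and glycolysis (9.0e-04), conceptus secretory genes (0.00557), syncytium and fusion (0.0138), stress and apoptosis (0.0138), interferon response (0.0138), transporters (0.0277) and cAMP response (0.0381). None of these calls was kept with an estimated correlation. Matrix and integrins, ancient PAGs, hypoxia and glycolysis, and syncytium and fusion each had adjusted p = 0.186 with an estimated correlation. Conceptus secretory genes, transporters and cAMP response had adjusted p = 0.228 with an estimated correlation, and S phase and stress genes had adjusted p = 0.248 with an estimated correlation. Interferon response had adjusted p = 0.295 and mitosis adjusted p = 0.458 with an estimated correlation. The call for cAMP response also ended with the size factors of DESeq2 (adjusted p = 0.0568), without replicate 1 (0.0534) and without replicate 2 (0.0599), in a range of 0.00170 to 0.0599 over its alternatives. Without clusters 5, 7 and 9 the calls for interferon response (adjusted p = 0.0630, range 0.00170 to 0.0630 over its alternatives) and transporters (0.0853, range 0.00837 to 0.0853) ended as well. Of markers of other cell types, 3 of 4 epiblast, 1 of 4 endoderm, 1 of 7 endothelial and 1 of 6 neural markers tested were higher, and 6 of 7 mesenchyme, 2 of 7 endothelial, 1 of 3 immune and 1 of 6 neural markers lower.

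Across all genes, edgeR called 3689 genes higher and 2520 lower in cluster 1, so that 59.4% of calls were higher. With the size factors of DESeq2 the counts were 2732 and 3207 (46.0% higher), as the median of all genes moved by -0.11 on the log2 scale, and the folds given for this comparison stand relative to that shift. The total fell from 6209 to 3594 without library as a block and to 342 without centring of the libraries and with clusters of at least 10 nuclei. At a clustering resolution of 0.3 the same rule chose a cluster with only 7.84% of its nuclei from cluster 1, in which 3163 genes were called and 23 of 44 named genes turned direction. Median UMIs per nucleus in cluster 1 were 1.04 ± 0.0849 times those of the other nuclei (SD, n = 3).

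The third comparison asked which nuclei resemble the starting stem cells. No cluster was named trophoblast stem-like, so cluster 6, with the highest mean log2 CPM of stem markers (5.45, against 5.37 in the next cluster), was compared with the others. By summed level, stem markers were not highest there, at 1574 ± 133 CPM against 2245 ± 338 in cluster 8, 1940 ± 70.2 in cluster 2 and 1735 ± 164 in cluster 10 (SD, n = 3). TSC transcription factors summed to 3488 ± 170 CPM in cluster 6 and to 4118 ± 220 in cluster 2. Without the condition on lowered markers the target would be cluster 3, in which 6570 genes were called and 6 of 47 named genes had the opposite direction. ELF5 and KLF5, transcription factors of trophoblast progenitors, were higher, as were several genes of glycolysis and hypoxia and a basement membrane collagen, while fibronectin and the keratin KRT8 were lower. KLF5 stood at 539 ± 121 against 275 ± 80.4 CPM, COL4A2 at 81.3 ± 7.03 against 26.7 ± 5.78 CPM and KRT8 at 771 ± 106 against 1281 ± 238 CPM (SD, n = 3).

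Of 17 TSC transcription factors tested, 9 rose and 2 fell. Cluster 6 was chosen by the level of 11 of them, of which 5 rose and 1 fell, and of the other 6 members 4 rose and 1 fell. ELF5 rose by 1.36 ± 0.17 (SE; adjusted p = 2.9e-07), KLF5 by 1.26 ± 0.13 and ESRRB by 0.67 ± 0.15, and TFAP2A (-0.61 ± 0.14) and TFAP2C (-0.30 ± 0.11) fell. CDX2 differed by 0.04 ± 0.12 (adjusted p = 0.89) and GATA3 by -0.12 ± 0.13 (adjusted p = 0.52). Of 13 epithelium genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with EPCAM at 0.84 ± 0.13, the E-cadherin gene CDH1 at 0.62 ± 0.13 and KRT8 at -0.53 ± 0.14. Of 21 matrix and integrin genes, 7 rose and 4 fell (8 and 6 adjusted over the list alone). ITGB6 rose by 1.71 ± 0.18 and COL4A2 by 1.68 ± 0.16, and FN1 (-1.42 ± 0.35), TIMP2 (-1.11 ± 0.22) and ITGA3 (-1.05 ± 0.26) fell. ITGA2 rose in the fit by 1.31 ± 0.23 although its mean level was lower, 71.7 ± 36.6 against 112 ± 25.8 CPM, and it stood at 747 CPM in cluster 8.

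Of 15 hypoxia and glycolysis genes, 9 rose and 1 fell. NDRG1 rose by 1.13 ± 0.26, the hexokinase gene HK2 by 1.05 ± 0.16 and PDK1, an inhibitor of pyruvate entry into mitochondrial oxidation, by 0.91 ± 0.12, and CA9 fell by 0.97 ± 0.24. Among 15 stress and apoptosis genes, 4 rose, including TRIB3 (1.70 ± 0.22), ATF3 (1.34 ± 0.23) and DDIT4 (0.88 ± 0.15), and 5 fell, including the p53 targets MDM2 (-0.66 ± 0.21) and GADD45A (-0.65 ± 0.12). The adaptor-like PAG1 row rose by 1.92 ± 0.19, and the glycoprotein row had no counts in cluster 6. STAR rose by 0.88 ± 0.13 and PAG2 fell by 0.74 ± 0.19. IFNT2 differed by 0.53 ± 0.34 (adjusted p = 0.24), MKI67 by -0.25 ± 0.12 (adjusted p = 0.12) and CYP11A1 by -0.22 ± 0.27 (adjusted p = 0.57). GCM1 and CSH2, near 0 outside cluster 10, did not differ (adjusted p = 0.092 and 0.26). Outside the lists and among genes not used for clustering, the intermediate filament gene NES (3.18 ± 0.27), ADGRF5 (2.82 ± 0.24), LRRC2 (2.69 ± 0.16), RASSF5 and CHST15 rose most. CITED1 (-1.59 ± 0.27), AIF1 (-1.57 ± 0.26), the mitochondrially encoded ND5 (-1.33 ± 0.27), ARHGAP22 and MRAS fell most.

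Of the other lists, mitosis had 0 higher and 3 lower of 24 (0 and 2 adjusted over the list alone), S phase 0 and 5 of 25, cytokinesis 6 and 0 of 11 (6 and 1 adjusted over the list alone) and endocycle and arrest 2 and 1 of 16. Hormones had 0 higher and 1 lower of 9, modern PAGs 0 and 4 of 14, ancient PAGs 0 and 3 of 5, conceptus secretory genes 0 and 4 of 10 and syncytium and fusion 3 and 2 of 17. Steroid synthesis had 3 higher and 3 lower of 13, cholesterol synthesis 1 and 5 of 15 (1 and 6 adjusted over the list alone), cAMP response 4 and 1 of 13, transporters 3 and 2 of 18, imprinted genes 2 and 1 of 13 and interferon response 1 and 0 of 10 (0 and 0 adjusted over the list alone). For each list in this comparison with a single pair of counts, the count adjusted over the list alone was the same. No list passed by camera, the lowest adjusted p being that of S phase (0.0596). TSC transcription factors and hypoxia genes had adjusted p = 0.118. By fry, which asks whether the genes of a set move 1 way on balance and compares them with no others, the TSC transcription factors were higher (adjusted p = 8.8e-05), a list that holds the markers by which the cluster was chosen. Hypoxia (1.4e-04), cAMP response (0.00501), cytokinesis (0.00598) and matrix genes (0.0156) were also higher by fry, and modern PAGs (0.00333), ancient PAGs (0.00598), hormones (0.00833) and S phase genes (0.0156) lower. Median, mean and camera direction differed in sign for syncytium and fusion, steroid synthesis, cAMP response and stress genes. All 4 epiblast, 3 of 4 endoderm, 2 of 7 endothelial and 2 of 6 neural markers tested were higher in cluster 6, and 1 of 7 mesenchyme and 1 of 6 neural markers lower.

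Across all genes, edgeR called 2738 genes higher and 1582 lower in cluster 6 (63.4% higher), against 2153 and 2213 (49.3% higher) with the size factors of DESeq2. In place of 4320 calls there were 2486 without replicate 2, 2160 without library as a block, 1823 without centring and 2728 without clusters 5, 7 and 9. With doublets kept the same rule chose a cluster with 1.54% of its nuclei from cluster 6, and 22 of 45 named genes turned direction. Median UMIs per nucleus in cluster 6 were 1.14 ± 0.170 times those of the other nuclei (SD, n = 3).

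To describe the course of differentiation, nuclei were ordered by diffusion pseudotime from cluster 6, an ordering by similarity and not a measured time. Mononucleate trophoblast markers rose along the ordering, with Spearman's rho over 10 bins of 0.745, 0.855 and 0.952 in replicates 1, 2 and 3 (0.851 ± 0.103, SD, n = 3), and peaked before the last bin. Summed stem markers also rose, away from the starting cluster chosen for them (1.00, 1.00 and 0.927), and cycling markers were lower towards the end (-0.891, -0.212 and -0.794, mean -0.632 ± 0.367), a direction that turned in replicate 2 over the first 9 bins (-0.850, 0.0833 and -0.717, mean -0.494). Binucleate markers reached 928, 165 and 852 CPM in the last bin, and their mean rho was 0.665 ± 0.188, or 0.539 over the first 9 bins (0.800, 0.283 and 0.533). Started from cluster 3 instead, the ordering gave cycling markers a mean rho of -0.204. Nuclei of cluster 1 had the lowest median rank (14.5%), below cluster 6 (26.3%) and cluster 3 (34.7%). Clusters 2, 8 and 10 lay late (85.2%, 96.5% and 98.7%). Clusters 9 and 11, which have no name, lay as late (98.7% and 99.7%). A late position was therefore not particular to the named clusters. Bins of 1 library are not independent, and no p-value is attached to these values.

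**Figure D3:**
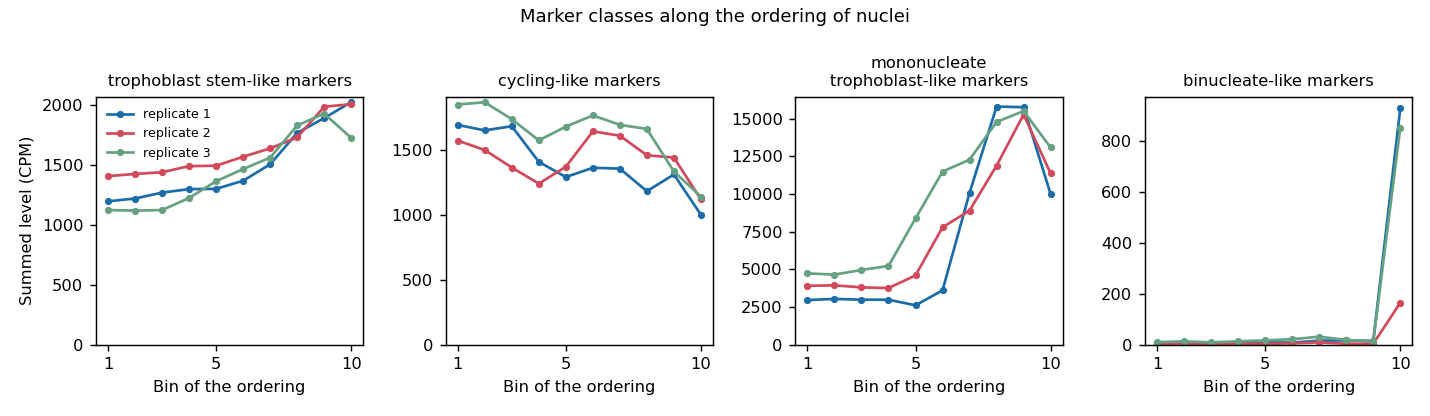
Summed level (CPM) of 4 marker sets in 10 equal bins of nuclei along the ordering, with 1 line per replicate. Binucleate markers reached 928, 165 and 852 CPM in the last bin of replicates 1, 2 and 3, and mononucleate trophoblast markers peaked in bins before it.

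UMIs per nucleus differed between classes. Whether nuclear RNA content differed was not tested, since UMIs also depend on capture. Except for cluster 5 itself, the other nuclei included those of the shallow cluster 5. Binucleate-like nuclei had medians of 1.28, 1.41 and 1.27 times those of the other nuclei in replicates 1, 2 and 3, and mononucleate trophoblast-like nuclei 1.18 ± 0.0685 times (SD, n = 3). Cluster 8, the smaller of the mononucleate clusters, had 1.68 ± 0.228 times the UMIs of the other nuclei, more than cluster 10, and cluster 5 only 0.216 ± 0.0387 times. Each of these ratios departed from 1 by more than its spread between libraries.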

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

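The contrast of cluster 11 with the other clusters and its tests for doublets and for another lineage were chosen after its result was seen. FOXI1, a transcription factor known from acid-secreting and ion-transporting epithelial cells, stood at 126 CPM in cluster 11 (89 counts in 117 nuclei), against 0.168 CPM elsewhere and a limit of 4.23 CPM that a count of 0 would allow. The cluster, too small for the comparisons, held 58, 20 and 39 nuclei of replicates 1, 2 and 3. It also carried proton pump subunit genes, with ATP6V1G3 at 996 CPM against 13.5 in the other clusters. FOXI1 and ATP6V1G3 were used for clustering, so their levels identify the cluster and do not test it. Doublets of other nuclei stay open. A mixture cannot exceed its parts, but for genes chosen in the other 2 libraries and not used for clustering, the highest level in another cluster had a median of 0.295, 0.586 and 0.676 times that in cluster 11 in replicates 1, 2 and 3, which does not decide it. The sum of the TSC transcription factors in cluster 11 was at least 0.768 times the library level in each library. This argues only against a lineage that lacks these factors. Doublets with trophoblast nuclei would carry them too, and TP63, among the highest members, is a factor of basal epithelial cells. Another lineage therefore stays open. A rare ion-transporting state of trophoblast was not tested.

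COL1A1, a fibrillar collagen of mesenchymal cells, stood at 5317 CPM in a cluster of 15 nuclei at resolution 0.3 that was not used in any comparison. These nuclei (4, 2 and 9 in replicates 1, 2 and 3) all lay in cluster 9 and also held KRT8 at 2296 CPM (908 elsewhere) and TKDP1 at 1893 CPM (3036 elsewhere). Their GATA3 level, 121 CPM from 3 counts, was at the limit that a count of 0 would allow and below the 599 CPM elsewhere, so their type was left open. In the nuclei removed for their doublet scores, binucleate cell hormones summed to 29.8 CPM (835 counts in 2506 nuclei), against 65.9 CPM in the nuclei kept.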

How the results depend on the processing

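The fits without clusters 5, 7 and 9, those that admit clusters of at least 10 nuclei and the version with names that ignore lowered markers were chosen after the results were seen; the other alternatives were planned. Recovery of 2-fold changes in simulated counts was lowest for the binucleate-like comparison (46%), to which replicate 2 gave 30 nuclei. Levels of the 20 analysed gene lists per library moved by less than the spread between libraries in all 80 alternative values. For the values with a replicate left out, this was fixed by arithmetic and does not test stability. A mean over the remaining libraries cannot move by as much as that spread. The values with the higher minimum of detected genes were not bound in this way. Of the alternative tests of lists, 392 kept their direction and side of the threshold, 43 passed that had not and 5 no longer passed. There were 2247 alternative values for the 139 pairs of a comparison and a gene named by the rule in the lists described. Of these, 1964 kept direction and side of the threshold, 177 no longer passed, 25 passed that had not and 81 turned. Pairs that passed in neither fit counted as kept whatever their direction. The lists described gene by gene were settled after these reversals were known. Over all 329 such pairs that the rule can name, in which a gene counts once per comparison, 220 of 5309 alternative values turned, of which 59, 23, 44 and 22 came from the cluster 6 comparison with doublets kept, at resolution 0.3, at resolution 1.0 and with names that ignore lowered markers, and 47 from the cluster 1 comparison at resolution 0.3.

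The binucleate-like comparison called 4119 genes, 2660 to 3631 with 1 replicate left out (2660 without replicate 1) and 2067 with nuclei thinned to 2000 UMIs and clusters of at least 10 nuclei. Fewer nuclei and counts entered the thinned fit by construction. The planned thinned, doublets-kept, resolution 0.3 and uncentred versions gave no value for this comparison, nor did the uncentred version for cluster 1, because the chosen cluster had fewer than 30 nuclei in a library. The cluster 1 comparison called 6209 genes, 4391 to 5144 with 1 replicate left out, 3594 with no replicate block, 3163 at resolution 0.3 and 342 without centring and with clusters of at least 10 nuclei. The cluster 6 comparison called 4320 genes, 2486 to 3419 with 1 replicate left out (2486 without replicate 2), 2160 with no replicate block, 1823 without centring, 2728 without clusters 5, 7 and 9 and 6570 with names that ignore lowered markers, which test cluster 3 instead. In the cluster 1 comparison, the adjusted p of the cAMP response list was 0.0568 with DESeq2 size factors and 0.0121 to 0.0599 with 1 replicate left out (0.0534 without replicate 1 and 0.0599 without replicate 2), within 0.00170 to 0.0599 over its alternatives. Without clusters 5, 7 and 9 the interferon response had adjusted p = 0.0630 (0.00170 to 0.0630 over its alternatives) and transporters 0.0853 (0.00837 to 0.0853). Beyond the choice of another cluster shown next, the cause was not tested.

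The mononucleate share was 26.8% of nuclei outside clusters 5, 7 and 9, 20.5% at resolution 0.3, 25.9% at resolution 1.0, 37.5% without centring and 32.4% with 4000 variable genes. Names that ignore lowered markers made 18.4% of nuclei trophoblast stem-like, with a UMI ratio of 0.957 and, in an ordering from cluster 3, a mean rho of 0.867 for stem and -0.204 for cycling markers. At resolution 0.3, 42.1% of nuclei were trophoblast stem-like, and with list genes in the clustering 16.9% were cycling-like. With doublets kept, the UMI ratio was 1.42 for binucleate-like nuclei and 0.722 for the cluster chosen by stem markers, and with at least 1000 genes it was 1.10 for mononucleate nuclei. With 5 bins the mean rho of binucleate markers was 0.933. The cause was not tested.

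Reversals came mainly from settings in which the rule chose other nuclei. With doublets kept, the cluster chosen by stem markers took 1.54% of its nuclei from cluster 6. It took 9.42% from cluster 6 at resolution 0.3 and 1.54% at resolution 1.0. At resolution 0.3 this cluster was named trophoblast stem-like, took 45.2% of its nuclei from cluster 1 and held 60.2% of cluster 6. The cluster chosen by cycling markers took 7.84% from cluster 1 at resolution 0.3, where 65.4% came from cluster 4. The cluster named cycling-like with list genes in the clustering took 57.1% of its nuclei from cluster 1 and held 46.0% of cluster 1. Of the genes named in the binucleate-like comparison, only the PAG1 row ENSBTAG00000014026 turned, with a range of -1.66 to 0.12 when 1 replicate was left out (0.12 without replicate 1), and 1 further gene that the rule can name turned in the thinned version with clusters of at least 10 nuclei.

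In the cluster 1 comparison, log2 changes that turned were GATA3 (-0.24) and PCNA (0.071) with doublets kept, PCNA (0.061) and STAR (0.75) with list genes in the clustering, POLA1 (-0.071) and STAR (1.41) without centring and with clusters of at least 10 nuclei, and PCNA (0.064) without clusters 5, 7 and 9. At resolution 0.3 they were ESRRB (-0.53), KLF5 (-0.27), ITGA6 (0.39), FGFR2 (0.56), TP63 (0.38), PAG12 (0.45), PAG11 (0.10), POLD3 (-0.18), ITGB3 (-0.54), ITGA5 (-0.38), TIMP3 (0.32), ADM (0.078), NDRG1 (0.88), EGLN3 (0.41), RDH12 (-0.65), GDPD2 (-0.23), TNFRSF19 (-0.54), RASSF9 (0.71), TXNIP (0.14), C15H11orf96 (1.05), PAG1 row ENSBTAG00000014026 (-0.20), IFNT2 (1.21) and CDX2 (-0.55).

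In the cluster 6 comparison with doublets kept, those that turned were TFAP2A (0.25), TFAP2C (0.037), TJP1 (-0.25), KRT8 (0.053), KRT18 (0.16), STAR (-0.0051), ITGB6 (-2.51), COL4A2 (-1.59), ITGA2 (-1.63), NDRG1 (-2.33), TRIB3 (-1.74), DDIT4 (-0.15), MDM2 (0.24), GADD45A (0.41), HSPA5 (0.068), NES (-4.14), ADGRF5 (-0.25), LRRC2 (-1.50), RASSF5 (-1.07), CHST15 (-0.86), ND5 (0.032) and GATA3 (0.38). At resolution 0.3 they were ITGB6 (-0.90), ITGA2 (-2.99), NDRG1 (-0.79), ATF3 (-0.63), NES (-1.85) and IFNT2 (-1.84). At resolution 1.0 they were TFAP2A (0.42), STAR (-0.17), ITGB6 (-1.72), COL4A2 (-1.28), ITGA2 (-1.18), NDRG1 (-1.70), TRIB3 (-1.51), DDIT4 (-0.25), MDM2 (0.50), GADD45A (0.32), NES (-3.95), LRRC2 (-0.87), RASSF5 (-0.65), CHST15 (-0.51) and GATA3 (0.54). Without clusters 5, 7 and 9, KRT18 turned (0.053). With names that ignore lowered markers they were ITGB6 (-0.63), ITGA2 (-3.27), NDRG1 (-0.40), ATF3 (-0.80), NES (-2.14) and IFNT2 (-2.41).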

Other observations

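The contrasts of clusters 2, 3, 8 and 11 and of the mononucleate class, the tests of the low binucleate-like share in replicate 2 and the free RNA and neural tests of cluster 5 were chosen after the results were seen, and so were the counts for each whole cluster, while the draws of other splits were fixed before. In an edgeR fit of all 11 clusters, mononucleate trophoblast-like nuclei were tested with clusters 2 and 8 at equal weight, although cluster 2 held 5958 of them and cluster 8 only 644. Of 21 matrix and integrin genes, 17 rose and 1 fell (17 and 2 adjusted over the list alone; camera adjusted p = 2.6e-19, and 8.2e-04 with an estimated correlation), but in cluster 2 alone 8 rose and 2 fell (adjusted p = 0.0523, and 0.850 with an estimated correlation). TIMP3 stood at 543 CPM in cluster 2 and 1347 CPM in cluster 8, FN1 at 151 and 1821 CPM and MMP9 at 5.76 and 412 CPM. All 10 interferon response genes tested rose in the class (camera adjusted p = 4.2e-04, and 0.238 with an estimated correlation), against 4 in cluster 2 alone (adjusted p = 0.525), and in cluster 8 they summed to 1105, 340 and 162 CPM in replicates 1, 2 and 3. Of 9 conceptus secretory genes, 6 rose and 1 fell in the class (8.6e-04, and 0.128 with an estimated correlation) and 4 rose and 2 fell in cluster 2 (0.389), a list that shares genes with the markers that named the class. Of 5 ancient PAGs, 4 rose and none fell in both, for the class with adjusted p = 5.5e-05 (0.0407 with an estimated correlation) and for cluster 2 with 2.2e-05 (0.0551 with an estimated correlation). Of 25 S phase genes, 1 rose and 16 fell in the class (3.9e-05, and 0.181 with an estimated correlation) and 2 rose and 12 fell in cluster 2 (0.0120, and 0.850 with an estimated correlation). Of markers of other cell types, 3 of 6 neural, 1 of 3 immune and 1 of 4 endoderm markers tested were higher in the class, and 2 of 6 neural, 1 of 3 immune, 1 of 4 endoderm, 2 of 7 endothelial and all 4 epiblast markers lower.

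Cluster 8, with 644 nuclei, stood out within that class. MMP9 stood at 412 against 6.21 CPM in the other clusters, FN1 at 1821 against 51.7 CPM, the collagen receptor gene ITGA2 at 747 against 38.1 CPM and SPP1, osteopontin, at 203 against 4.19 CPM. Of its 21 matrix genes, 18 rose and none fell (19 and 0 adjusted over the list alone; camera adjusted p = 1.5e-30, and 3.3e-05 with an estimated correlation). Of markers of other cell types, 2 of 3 immune, 2 of 7 mesenchyme, 3 of 6 neural, 1 of 4 endoderm and 1 of 7 endothelial markers tested were also higher in cluster 8. Lower there were 2 of 6 neural, 1 of 4 endoderm, 1 of 7 endothelial and all 4 epiblast markers. Cluster 3 differed the other way, with 3 of 21 matrix genes higher and 15 lower and all 5 ancient PAGs lower (camera adjusted p = 5.1e-04 for both lists, and 0.399 and 0.269 with an estimated correlation). FLT1, the receptor for vascular endothelial growth factor, was higher there by 3.18 ± 0.18, GATA6 by 2.04 ± 0.14 and ESRRB by 2.06 ± 0.12. Of markers of other cell types, 3 of 4 epiblast, 2 of 4 endoderm, 1 of 7 endothelial and 1 of 6 neural markers tested were higher in cluster 3. Lower there were 3 of 7 mesenchyme, 2 of 3 immune, 2 of 6 neural and 1 of 7 endothelial markers.

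Replicate 2 had the lowest share of binucleate-like nuclei, 0.279% against 1.58% and 0.972%. Lower depth is argued against, since replicate 2 was deeper than replicate 3, though not than replicate 1. Medians in kept nuclei were 5047, 4316.5 and 4017 UMIs in replicates 1, 2 and 3. Among nuclei with at least 2000 UMIs the share of replicate 2 was 0.323%, below the lower bound of 0.816% for replicate 3. Removal of doublets is argued against by a share of 0.205% with doublets kept, below the lower bound of 0.645% for replicate 3. Misplaced nuclei are argued against, because the hormone level of the whole library was 0.162 times the lower of the other libraries. What remains open is a difference between cultures or in the recovery of nuclei, and no biological explanation was tested with 1 group.

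Cluster 5 held shallow nuclei, 0.541% of replicate 1 against 13.9% and 10.9% of replicates 2 and 3. Free RNA in droplets without a nucleus stays open. In cluster 5, 65 genes of at least 20 CPM stood at 4 times the library level or more in replicates 2 and 3 both. This goes against free RNA drawn evenly from the library as its whole content. The count did not exclude clustering genes, which favours it, and the filtered matrices hold no empty droplets that would show the make-up of free RNA. Neural cells as its whole content are argued against by MAP2, TUBB3 and STMN2, which summed to at most 28.4 CPM in any library, with STMN2 at 4.17 CPM against 6.78 in the whole data. A neural part stays open, since MAP2 (12.2 against 2.98 CPM) and RBFOX3 (29.2 against 3.82 CPM) were raised. Neural markers also summed to more than in any other cluster (54.6 ± 9.64 CPM, SD, n = 3). CSMD2, PKHD1, CADPS and RBFOX3 led the cluster, and all but RBFOX3 were used for clustering. Damaged or partial nuclei stay open and were not tested, as does any biological explanation.

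Other clusters were put in the place of the tested one within each library, in 30 draws that include the real one. For the binucleate-like comparison, 2 of 30 draws called as many genes, the real value being 4119 and the highest other 7092. That draw put cluster 9 whole in its place, so the count compares real clusters and cannot exclude chance. For cluster 1 it was 2 of 30 as well, with 6209 and a highest other of 6570. For cluster 6 only the real draw (1 of 30) reached 4320, with a highest other of 4112, but no draw put 1 other cluster in its place in every library, so this count does not exclude chance. The draws that exceeded the real value in the first 2 comparisons did so, with cluster 9 and cluster 3. They show only that these clusters also differ from the rest. Draws that mixed clusters called at most 2686 and 4102 genes in these 2 comparisons. Tested whole in the same fit, 6 of the 9 other clusters called more genes than cluster 6, from 4638 in cluster 4 to 7092 in cluster 9.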
